A study of Mus musculus with 4 samples.

How the data were processed

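The samples are RNA precipitated from corticohippocampal lysate of mice, per the labels, with 2 arrays for CPEB3 IgG and 2 arrays for control IgG, grouped by the sample titles. Per the labels' protocols, RNA was extracted with acidic phenol and chloroform, and 0.2 ug per sample was amplified and labelled with Cy3 by a low-input kit. No input or total lysate array was analysed here, so every value is relative to control IgG. The labels do not say whether replicates came from separate animals or lysates, so p-values measure only the spread between these samples, which may be technical.

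The deposited files hold spot intensities of 1 colour from Agilent Feature Extraction 10.5.1.1, per the file headers. Per the file headers, the processed intensity is the mean spot brightness after background subtraction and spatial detrending within the array, with substitute values for spots near background, and it is not normalised between arrays. The deposited mean and local background intensities of each spot were used only for an alternative. The test that the authors used is not given in the sources used here. Probe coordinates come from the files, on mm9 per the file headers. No genome sequence or annotation of that build was used, so exon and UTR positions were not analysed here.

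Each array has 62976 spots, of which 3671 are control spots and 59305 carry 55681 distinct probes. Control spots and spots flagged as outliers (133 and 123 with CPEB3 IgG, 156 and 223 with control IgG) were left out, and 63 probes without a value on all arrays could not be fitted. The main value is log2 of the processed signal minus the 75th percentile of the array, averaged over spots of the same probe. Probes well above background on at least 2 of the 4 arrays were kept (40616 probes). Symbols were updated through RefSeq accessions without their versions with a table of the GRCm38 assembly, used for names only, which matched 27509 probes and renamed 2017, while 28172 kept the name in the files. Each gene was represented by its brightest probe, and 8297 of the 27687 entries had several probes.

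Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no block). They were called after Benjamini-Hochberg adjustment at a threshold of adjusted p 0.05. Gene lists were tested with camera of limma, with a preset correlation of 0.01 between genes and, beside it, an estimated correlation, over 27 lists of at least 5 measured genes. Except where said otherwise, the lists, the groups, the tests, the alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names Nr3c1, Cpeb3, all reported CPEB3 targets and the 12 largest positive and 8 largest negative differences among genes that passed, were well above background on all 4 arrays and had groups that did not overlap. It also names up to 4 higher genes that passed but were not well above background on either control array, and up to 3 passing members of each list with the largest differences, or 2 with the smallest p where none passed. Some genes that the rule takes are not reported here. Other members of a list (the further Cpeb genes, Fxr1, Rbfox1, Jun, Nr4a3, Xbp1, Cox8a, Sdhc, Psmd7, Psma3, Ank3 and Hsp90aa1) were chosen after their values were seen, as members that moved with or against their list, and were refitted in every setting like the others. A gene not above background in a group has only a bound, taken as the bright group's mean over the mean, per array of the dim group, of the higher of its own signal and the lowest signal that was well above background. Intervals of 95% for log2 differences use the moderated degrees of freedom of the fit.

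Alternatives were normexp background correction with offset 50, quantile, median, cyclic loess, spike-in and no scaling, no filter on dim probes or a filter on all 4 arrays, the mean of a gene's probes, an intensity trend in the variance prior, and the replicate number as a block. Each array was also left out in turn, and further alternatives were stricter thresholds (adjusted p 0.01, or a 2-fold difference) and an estimated correlation for the lists. All arrays were on 1 slide and in 1 scan, so a slide or scan block could not be fitted. Replicate arrays were compared before averaging and shared 0 identical spot values within either group.

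The fit was tested on simulated arrays with the levels and spread of this comparison over 27687 genes. With 200 genes changed, 0 of 50 were recovered at 1.5-fold, 0 of 50 at 2-fold, 0 of 50 at 4-fold and 29 of 50 at 8-fold, with 2 false calls, while unadjusted p under 0.05 was reached by 4.96% of unchanged genes. With 10908 genes changed by 2.4-fold, as many as the comparison called, 84.3% were recovered, with 262 false calls. In a simulation of camera over the same genes, the list of moved genes passed, as did 7 of 200 unmoved lists before adjustment. The noise of each simulated gene was drawn independently, so the simulation does not test the preset correlation where genes vary together. In the data, the estimated correlation was 0.452 for oxidative phosphorylation genes, 0.199 for proteasome genes and −0.005 for glutamate receptor genes. Bootstrap intervals used 2000 draws and trends a loess span of 0.5. Bootstrap draws took genes or probe pairs as if independent, so these intervals leave out the spread between arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.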

Results

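The data are a ribonucleoprotein immunoprecipitation read out on arrays. Lysate of cortex and hippocampus from 8-week-old male C57BL/6 mice, a common inbred laboratory strain, was mixed for 3 h with beads that carried either an antibody against CPEB3 or a control antibody. CPEB3 is cytoplasmic polyadenylation element binding protein 3, an RNA-binding protein that regulates the translation of neuronal mRNAs. The RNA brought down by each antibody was amplified, labelled with Cy3 and hybridised to a 1-colour Agilent mouse array, with 2 arrays for CPEB3 IgG and 2 arrays for control IgG. Of 55681 probes, 70.0% and 68.0% were well above background in CPEB3 IgG replicates 1 and 2, and 73.4% and 73.2% in control IgG replicates 1 and 2. The 75th percentile of the signal was 507 and 353 units with CPEB3 IgG and 443 and 425 units with control IgG, and 0 spots were saturated. The number of arrays limits the precision of every value. Levels are log2 signals relative to the 75th percentile of the same array, and every difference is CPEB3 IgG minus control IgG, so it compares shares of the precipitated RNA and not amounts in the tissue.

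The study's title names Nr3c1 mRNA, which encodes the glucocorticoid receptor, and the comparison asks which mRNAs came down with the CPEB3 antibody more than with the control antibody. Nr3c1 was 2.09-fold higher with CPEB3 IgG at the brighter of its 2 probes. The level was 5.15 ± 0.07 (SD, n = 2) with CPEB3 IgG and 4.09 ± 0.12 (SD, n = 2) with control IgG. The log2 difference was 1.06 ± 0.16 (SE, limma adjusted p = 0.0112). This probe lies on chromosome 18 from 39571641 to 39571700 in mm9, at position 4827 of the transcript. Its sequence is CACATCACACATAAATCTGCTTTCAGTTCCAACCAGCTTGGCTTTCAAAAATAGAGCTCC. The other Nr3c1 probe lies 2542 nt nearer the 5′ end, at position 2285 (39574183 to 39574242). Its sequence is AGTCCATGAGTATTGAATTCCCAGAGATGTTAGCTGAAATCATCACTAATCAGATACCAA. There the level was 0.21 ± 0.29 (SD, n = 2) with CPEB3 IgG and 0.50 ± 0.11 (SD, n = 2) with control IgG. The log2 difference was −0.29 (95% interval −0.86 to 0.28, adjusted p = 0.345). The call of the brighter probe was lost without scaling (log2 difference 1.03, adjusted p = 0.0916). It was also lost with CPEB3 IgG replicate 1 left out (1.01, adjusted p = 0.0665) and with CPEB3 IgG replicate 2 left out (1.11, adjusted p = 0.0555). With the mean of both probes it was lost (0.39, adjusted p = 0.135).

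Cpeb3 mRNA itself was 7.71-fold higher in the CPEB3 precipitate. Its levels were 4.04 ± 0.26 and 1.09 ± 0.26 (SD, n = 2 each), with a log2 difference of 2.95 ± 0.23 (SE, adjusted p = 0.00386). It ranked 129 from the top of 27687 array entries, and Nr3c1 ranked 3667. The mRNAs of the other members of the family were also higher, Cpeb2 by 1.63 ± 0.15, Cpeb4 by 1.51 ± 0.15 and Cpeb1 by 1.09 ± 0.19 on the log2 scale (SE). The call of Cpeb1 was lost with CPEB3 IgG replicate 2 left out (0.92) and without scaling (1.05).

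Of 10 mRNAs named before the data were examined as reported CPEB3 targets, 4 rose, 1 fell and 5 did not pass the test. Adjusted over the list alone, 4 rose and 2 fell. Egfr, the epidermal growth factor receptor, was 3.87-fold higher (log2 difference 1.95 ± 0.23). Sumo2, a small ubiquitin-like modifier, was 3.77-fold higher (1.91 ± 0.17), and all 5 of its probes rose, by 0.70 to 1.91. The AMPA receptor subunits Gria2 and Gria1 were higher by 1.503 ± 0.161 and 0.72 ± 0.17. The call of Gria1 was lost with each array left out in turn, at 0.66 and 0.78 without CPEB3 IgG replicates 1 and 2 and at 0.84 and 0.59 without control IgG replicates 1 and 2. It was also lost with quantile (0.56), spike-in (1.36) or no scaling (0.68) and without the filter on dim probes, and that of Gria2 with the mean of its probes (0.67). Actb, which encodes cytoplasmic actin, was 4.44-fold lower (−2.15 ± 0.15). The NMDA receptor subunits Grin1 (0.27 ± 0.17), Grin2b (−0.18 ± 0.18) and Grin2a (−0.66 ± 0.19, adjusted p = 0.0535), the postsynaptic scaffold Dlg4 (0.08 ± 0.19) and the ion channel Trpv1 (−0.31 ± 0.29) did not pass. The signs of Grin2b, Dlg4 and Trpv1 turned with the scaling. Second probes nearer the 5′ end gave −0.57 for Egfr (adjusted p = 0.0744), −0.16 for Gria2 (adjusted p = 0.727), 0.011 for Grin1 (adjusted p = 0.980) and −0.093 for Grin2a (adjusted p = 0.707). A second Grin2b probe, nearer the 3′ end, gave 0.57 (adjusted p = 0.0547). As a group the 10 genes did not pass the list test (camera adjusted p = 0.400).

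**Figure D1:**
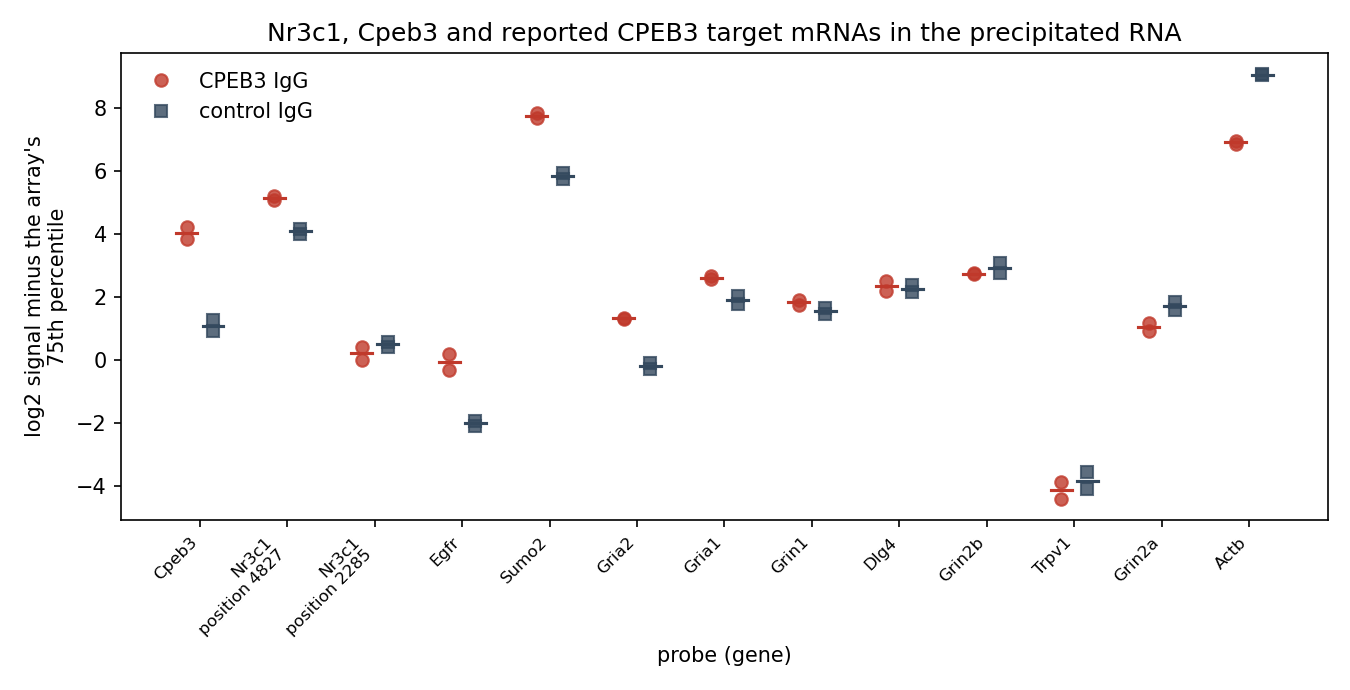
Log2 signal relative to the 75th percentile of the array (vertical axis) of Nr3c1, Cpeb3 and the reported target mRNAs (horizontal axis), with each array as a point (circles CPEB3 IgG, squares control IgG, n = 2 each) and the group mean as a bar. Nr3c1 is shown by both probes, with a difference of 1.06 at transcript position 4827 and −0.29 at position 2285, while Cpeb3 differs by 2.95 and Actb by −2.15.

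Of named mRNAs well above background on all 4 arrays, the most enriched were Tmem39a, a transmembrane protein, at 19.6-fold (95% interval 13.8 to 27.7), and B4galt3, a galactosyltransferase of glycan synthesis, at 17.3-fold (11.5 to 26.0). Sppl3, an intramembrane protease, was 13.9-fold higher (10.6 to 18.4), with levels of 7.40 ± 0.02 and 3.60 ± 0.06 (SD, n = 2 each). They were followed by the thiamine transporter Slc19a2 (log2 difference 3.78 ± 0.20, SE), the Notch-responsive repressor Hes1 (3.78 ± 0.32), Vasn (3.77 ± 0.16), and the cadherin Cdh4 (3.77 ± 0.33). The rest of the 12 were Bcl7c (3.70 ± 0.15), the ciliary rootlet protein Crocc (3.68 ± 0.17), Cdca4 (3.64 ± 0.17), the F-box protein Fbxl12 (3.61 ± 0.24) and the RNA-binding protein Mex3d (3.61 ± 0.15). Second probes were also called higher for B4galt3 (3.76), Mex3d (2.95), Sppl3 (2.397) and Cdh4 (1.09), whereas those of Vasn (0.37, adjusted p = 0.221) and Bcl7c (0.16, adjusted p = 0.497) were not. The morphogen Shh was not well above background on either control array and was at least 10.7-fold higher with CPEB3 IgG (adjusted p = 0.00386). Likewise, Wdr19 was at least 6.54-fold and Supt7l at least 4.49-fold higher (adjusted p = 0.00386 each), and Rhbdf2 at least 7.09-fold (adjusted p = 0.0204). The call of Rhbdf2 was lost without CPEB3 IgG replicate 1 (fitted difference 3.62) or 2 (3.95).

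Under the same limit the most depleted were Htatsf1, a transcription elongation and splicing factor, at 14.2-fold lower (95% interval 8.39 to 23.9), and the inducible heat shock protein Hspa1a (log2 difference −3.75 ± 0.34, SE). Phgdh, the enzyme that starts serine synthesis, was lower by −3.69 ± 0.21 at its brightest probe, which the files place on chromosome 17, and by −3.75 and −4.07 at its 2 probes on chromosome 3. Lgals9 (−3.66 ± 0.15), Rtf2 (−3.53 ± 0.16), the peptidase Thop1 (−3.40 ± 0.21) and the neuronal ubiquitin hydrolase Uchl1 (−3.35 ± 0.24) followed. The noncoding RNA Tslrn1 (−3.49 ± 0.71) had a control SD of 1.44 and lost its call without CPEB3 IgG replicate 1 (−3.52) or 2 (−3.45).

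In all, 5309 array entries were higher and 5599 lower with CPEB3 IgG out of 27687 tested (limma, adjusted p under 0.05), with a median fold of 2.48 among the higher and 2.23 among the lower. Among the 16991 entries matched to a RefSeq transcript, 4351 were higher and 3376 lower, while among 3972 entries named only by a genomic interval 243 were higher and 673 lower. Replicate arrays correlated at 0.988 with CPEB3 IgG and 0.979 with control IgG over these entries, and arrays of different groups at 0.925 to 0.938 (across genes, which are not independent replicates). The higher entries made up 48.7% of the calls, 68.4% when arrays were scaled on their median and 86.2% when they were scaled on the spike-in RNA. The mean log2 spike-in signal was 13.11 and 13.43 with CPEB3 IgG and 13.97 and 13.94 with control IgG (replicates 1 and 2). The 75th percentile ran the other way between the CPEB3 IgG replicates (507 and 353 units), so spike-in scaling set them further apart. A call lost with it can thus reflect a wider spread and not a smaller difference, as for Gria1 (0.72, and 1.36 with spike-in scaling). With CPEB3 IgG replicate 1 left out the counts were 2492 higher and 2019 lower, and with replicate 2 left out they were 2906 and 2369. The first number of the slide position separated the groups, so slide position and antibody cannot be told apart.

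Ionotropic glutamate receptor genes rose together, with 13 higher and 0 lower of 22 measured, or 13 and 1 adjusted over the list alone (camera adjusted p = 9.98e-05). With an estimated correlation the adjusted p = 0.355. The kainate receptor subunits Grik3 (3.39 ± 0.21) and Grik1 (2.93 ± 0.20) and the AMPA receptor subunit Gria3 (2.08 ± 0.17) led the list, and second probes of these genes gave −0.60, 0.02 and 0.73, none of which passed. RNA-binding regulators of translation rose as well, with 19 higher and 2 lower of 30, and 19 and 2 adjusted over the list alone (adjusted p = 5.68e-05, and adjusted p = 0.355 with an estimated correlation). Besides Cpeb3 they include the deadenylation cofactors Tob2 (2.34 ± 0.16) and Btg2 (2.28 ± 0.15), while Fxr1 (−1.02 ± 0.16) and Rbfox1 (−0.68 ± 0.15) fell. The call of Fxr1 was lost without CPEB3 IgG replicate 1 (−1.11) or 2 (−0.92), and that of Rbfox1 without any one of the 4 arrays (−0.71 to −0.65). With spike-in scaling both were lost (−0.37 and −0.034), and Rbfox1 lost its call in 10 settings in all.

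Immediate early genes, which respond fast to neuronal activity, were higher for 12 and lower for 2 of 20, or 13 and 3 adjusted over the list alone (adjusted p = 0.000956, and adjusted p = 0.355 with an estimated correlation). The transcription factors Npas4 (2.87 ± 0.16) and Egr2 (2.29 ± 0.28) rose most, with Btg2, and Jun (−1.16 ± 0.19) and Nr4a3 (−0.84 ± 0.23) fell. Of the chaperones and folding enzymes of the endoplasmic reticulum, 12 were higher and 1 lower of 18, or 14 and 1 adjusted over the list alone (adjusted p = 8.19e-05, and adjusted p = 0.355 with an estimated correlation). Pdia6 (2.34 ± 0.17), Dnajb11 (2.21 ± 0.15) and Hspa5 (2.11 ± 0.16) led, and the transcription factor Xbp1 (−0.62 ± 0.15) fell. Without any one of the 4 arrays the calls of Nr4a3 (−1.09 to −0.58) and Xbp1 (−0.68 to −0.56) were lost, and that of Jun was lost without CPEB3 IgG replicate 1 (−1.155) or 2 (−1.164). With spike-in scaling Xbp1 lay at 0.025 and the calls of Jun (−0.51) and Nr4a3 (−0.19) were lost, the latter in 12 settings in all. A second probe of Pdia6 gave −0.26 (adjusted p = 0.298).

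Voltage-gated potassium channel genes were higher for 8 and lower for 1 of 21, and the same counts held adjusted over the list alone (adjusted p = 0.00759, and adjusted p = 0.355 with an estimated correlation), with Kcnc1 at 2.50 ± 0.16, Kcnh1 at 1.78 ± 0.21 and Kcnd3 at 1.41 ± 0.29, a call that was lost without CPEB3 IgG replicate 1 (1.09) or control IgG replicate 2 (1.21). Chromatin and transcription regulators were higher for 10 and lower for 3 of 30, also adjusted over the list alone (adjusted p = 0.0174, and adjusted p = 0.476 with an estimated correlation). The histone methyltransferase Kmt2c (3.11 ± 0.15), the deacetylase Hdac9 (2.60 ± 0.15) and the DNA demethylating enzyme Tet2 (2.43 ± 0.15) led this list. E3 ubiquitin ligase genes were higher for 15 and lower for 6 of 32, or 15 and 7 adjusted over the list alone (adjusted p = 0.0243, and adjusted p = 0.371 with an estimated correlation). Huwe1 (2.02 ± 0.15) and Nedd4l (1.92 ± 0.17) rose and Cul3 (−1.93 ± 0.15) fell, a call that was lost with spike-in scaling (−1.29). Second probes were called higher for Tet2 (2.31) and Nedd4l (0.97) and lower for Hdac9 (−0.82, adjusted p = 0.0411), and the other probes of Tet2 (0.31), Kcnc1 (0.31 and −0.34) and Kcnd3 (−0.13) were not called. Without control IgG replicate 2 these 3 lists had adjusted p values of 0.0721, 0.0721 and 0.108. Over the 17215 genes with a known position of the probe on the transcript they had 0.079, 0.148 and 0.156, and 0.827, 0.924 and 0.993 once the trend with that position was removed. The glutamate receptor list passed over those genes (0.00504) but not with the trend removed (0.0717). The RNA-binding (0.00994), immediate early (0.00686) and endoplasmic reticulum (0.000894) lists then still passed, as did oxidative phosphorylation (6.03e-06), proteasome (0.000179) and cytoskeletal (5.25e-05) genes. The tests over genes with a known position used the preset correlation only.

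Nuclear genes of oxidative phosphorylation fell as a group, with 32 lower and 2 higher of 40, and the same counts adjusted over the list alone (adjusted p = 1.23e-08, and adjusted p = 0.554 with an estimated correlation). Ndufb7 (−2.57 ± 0.18) and Ndufs8 (−2.45 ± 0.17) of complex I and Uqcrc1 (−2.47 ± 0.17) of complex III fell most, and Cox8a (0.77 ± 0.18) and Sdhc (0.67 ± 0.15) rose. Proteasome subunits were lower for 23 and higher for 2 of 31, and the same counts held adjusted over the list alone (adjusted p = 2.74e-05, and adjusted p = 0.476 with an estimated correlation). Psmd13 (−3.22 ± 0.22), Psmc4 (−2.69 ± 0.17) and Psmb7 (−2.67 ± 0.25) fell most, and Psmd7 (1.93 ± 0.15) and Psma3 (0.93 ± 0.17) rose. Without any one of the 4 arrays the calls of Cox8a (0.62 to 0.92), Sdhc (0.63 to 0.72) and Psma3 (0.81 to 1.05) were lost, as they were without scaling (0.73, 0.64 and 0.89). Cox8a and Sdhc also lost their calls with spike-in scaling (1.41 and 1.32) and without the filter on dim probes (0.77 and 0.67). Cytoskeletal protein genes were lower for 18 and higher for 4 of 28, again also adjusted over the list alone (adjusted p = 0.00759, and adjusted p = 0.355 with an estimated correlation). They include the neurofilament subunit Nefm (−3.12 ± 0.27) and the tubulins Tubb4a (−3.09 ± 0.20) and Tuba1a (−2.74 ± 0.19), while the axonal scaffold Ank3 (2.14 ± 0.15) rose, a call that was lost with the mean of its probes (0.085).

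**Figure D2:**
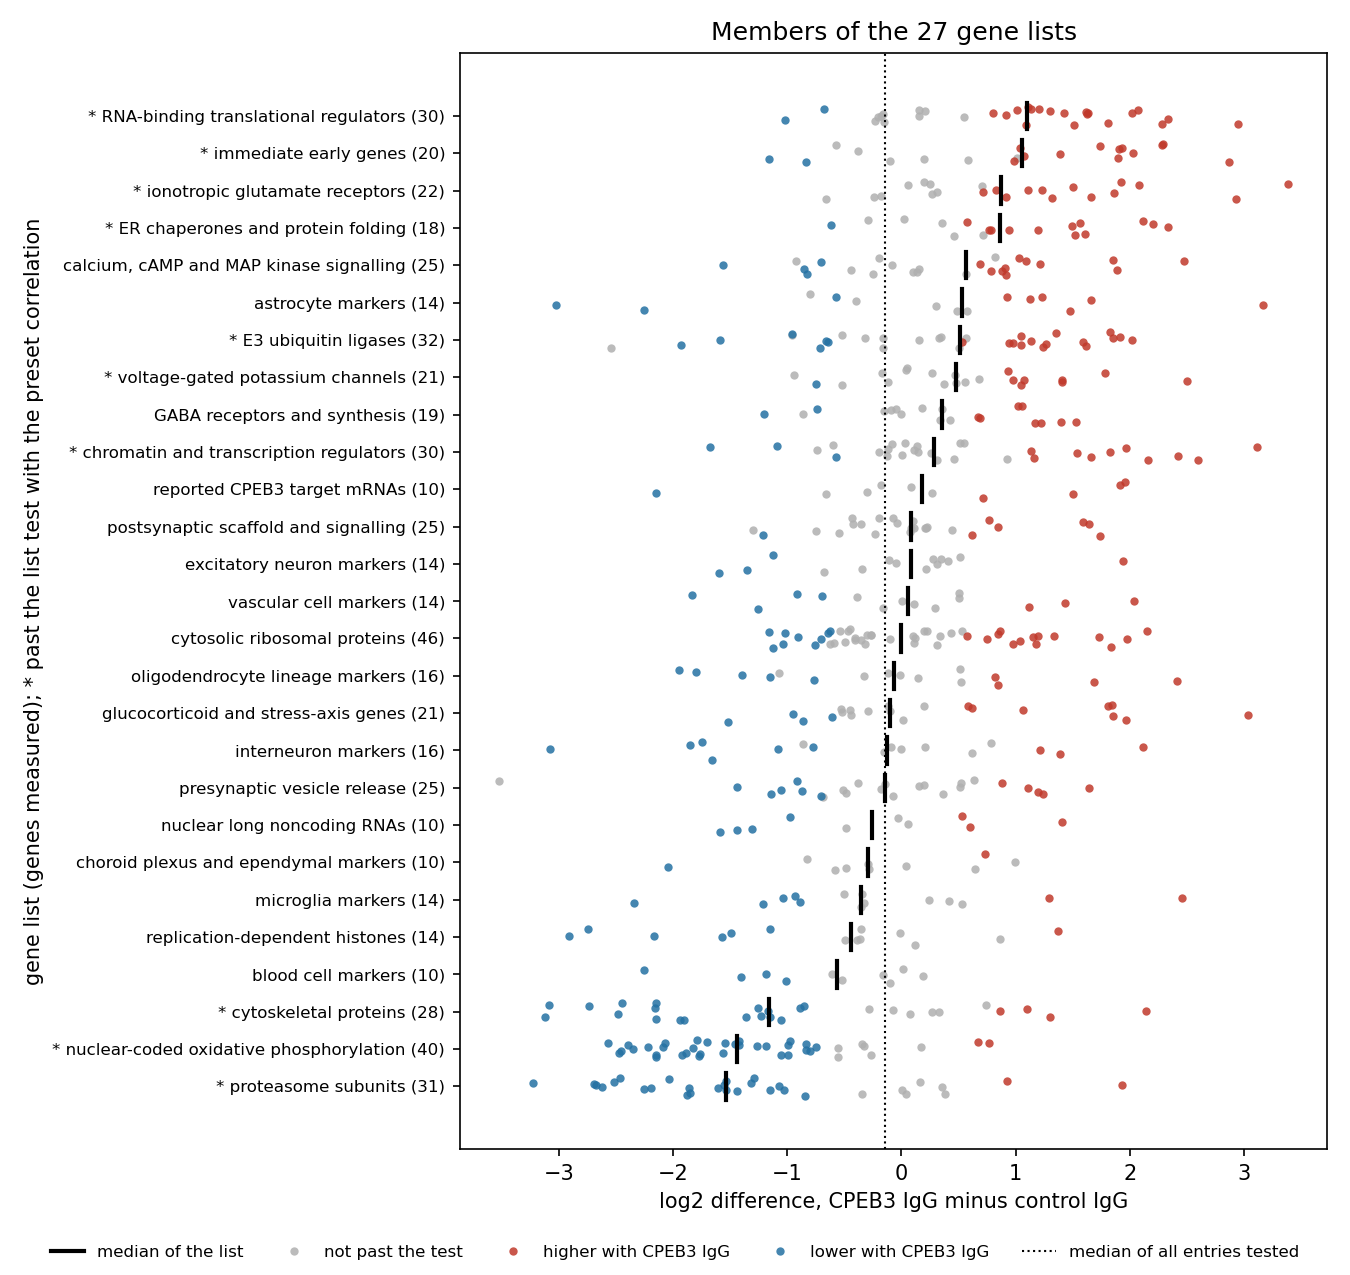
Log2 difference, CPEB3 IgG minus control IgG (horizontal axis), of each measured member of the 27 gene lists (vertical axis, with the number measured), coloured by whether and in which direction it passed adjusted p 0.05, with the list's median as a bar and the median of all 27687 entries (−0.14) as a dotted line. Lists with an asterisk passed the list test with the preset correlation, and the medians run from −1.53 for proteasome subunits to 1.097 for RNA-binding translational regulators.

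In total 10 of the 27 lists passed, 7 upward and 3 downward, and 0 passed with an estimated correlation, with which camera gave 3 lists an unadjusted p under 0.05. Glucocorticoid and stress-axis genes, the list that holds Nr3c1, did not pass (adjusted p = 0.584), with 8 higher and 4 lower of 21, or 8 and 5 adjusted over the list alone. Its members included the corticotropin-releasing hormone Crh (3.04 ± 0.35), the clock gene Per1 (1.97 ± 0.19) and the receptor Crhr1 (1.85 ± 0.17) among the higher, and Hsp90aa1 (−1.52 ± 0.18), a chaperone of the glucocorticoid receptor, among the lower. A second probe was also higher for Crhr1 (1.66) and not called for Per1 (0.077), and Hsp90aa1 lost its call with spike-in scaling (−0.87). GABA receptor and synthesis genes had 8 higher and 2 lower of 19, 8 and 3 adjusted over the list alone (adjusted p = 0.0643), with Gabra5 at 1.40 ± 0.15 and Gabra4 at 1.53 ± 0.25. The call of Gabra4 was lost without CPEB3 IgG replicate 2 (1.25).

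Calcium, cAMP and MAP kinase genes had 11 and 4 of 25, 13 and 4 adjusted over the list alone (adjusted p = 0.0643), led by Prkar2b (2.47 ± 0.18), Pde4b (1.89 ± 0.16) and Crem (1.85 ± 0.17). Both other probes of Prkar2b were higher too (1.805 and 1.68), whereas Pde4b and Crem lost their calls with the mean of their probes (0.042 and 0.72), and 1 of the other Pde4b probes was called lower (−1.28, adjusted p = 0.0121). The other Crem probes (−0.10 and 0.42) were not called. Postsynaptic scaffold and signalling genes had 6 and 1 of 25, 5 and 1 adjusted over the list alone (adjusted p = 0.444), led by Homer1 (1.74 ± 0.17), Camk2g (1.64 ± 0.15) and Shank3 (1.59 ± 0.19). Homer1 and Shank3 lost their calls with the mean of their probes (0.12 and 0.31). The other Homer1 probes lay between −0.55 and 0.21, none of them called, and the second Shank3 probe was called lower (−0.97, adjusted p = 0.0392). Presynaptic release genes had 5 and 6 of 25 by either adjustment, the list alone included (adjusted p = 0.938), with the adhesion molecules Nrxn2 (1.64 ± 0.20) and Nrxn3 (1.24 ± 0.20) among the higher. Nrxn2 lost its call without CPEB3 IgG replicate 1 (1.65) and Nrxn3 without replicate 1 (1.11) or 2 (1.38) and with the mean of its probes (0.16). Cytosolic ribosomal protein genes had 14 and 9 of 46, 14 and 10 adjusted over the list alone (adjusted p = 0.515), with Rpl22 (2.16 ± 0.19), Rpl30 (1.98 ± 0.16) and Rplp2 (1.84 ± 0.17) among the higher. Replication-dependent histone genes had 1 and 6 of 14 by either adjustment (adjusted p = 0.0662), among them H1f4 at −2.74 ± 0.20, H4c3 at −2.17 ± 0.16, and H3c1, which was not well above background with CPEB3 IgG, at least 2.66-fold lower. H3c1 lost its call with normexp background correction (−0.498). The histone list, though not past the test in the main setting, passed downward in 8 of 17 settings with the preset correlation. The list named nuclear long noncoding RNAs had 3 and 4 of 10 by either adjustment (adjusted p = 0.748), with Kcnq1ot1 at −1.59 ± 0.18, Meg3 at −1.44 ± 0.40 and Gas5 at 1.41 ± 0.17. Where these RNAs lay in the cell was not measured, so the list does not show how nuclear RNA behaved. Gas5 turned to −0.047 with the mean of its probes, 1 of which was called lower (−1.21, adjusted p = 0.0162), and Kcnq1ot1 lost its call with spike-in scaling (−0.95). Meg3 lost its call without CPEB3 IgG replicate 1 (−1.63), CPEB3 IgG replicate 2 (−1.25) or control IgG replicate 1 (−0.93), and in 6 settings in all. The median and mean of a list differed in sign for the glucocorticoid (−0.10 and 0.31) and ribosomal (−0.00057 and 0.14) lists. Both lay below 0 for the presynaptic list (−0.145 and −0.147) although its test, which is relative to the other genes, pointed upward.

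None of the 8 lists of cell type markers passed, and camera gave 0 of them an unadjusted p under 0.05. Astrocyte markers had 6 higher and 3 lower of 14, 7 and 4 adjusted over the list alone (adjusted p = 0.244), and their members moved far in opposite directions, from the glutamate transporter Slc1a3 (3.16 ± 0.37) to Aldoc (−2.26 ± 0.22) and Aldh1l1 (−3.03 ± 0.23). Excitatory neuron markers had 1 and 3 of 14 by either adjustment (adjusted p = 0.950), with the glutamate transporter Slc17a6 at 1.94 ± 0.19 and the transcription factors Tbr1 at −1.60 ± 0.31 and Bcl11b at −1.35 ± 0.18. A second probe of Bcl11b was higher (0.98). Interneuron markers had 3 and 6 of 16, 4 and 7 adjusted over the list alone (adjusted p = 0.662), with Calb2 at −3.08 ± 0.82, Dlx2 at 2.12 ± 0.57 and the neuropeptide Npy at −1.86 ± 0.18. Oligodendrocyte lineage markers had 4 and 5 of 16, 5 and 6 adjusted over the list alone (adjusted p = 0.950), with the progenitor receptor Pdgfra at 2.42 ± 0.16 and the myelin genes Ermn and Cnp at −1.95 ± 0.27 and −1.80 ± 0.22. Microglia markers had 2 and 5 of 14, 3 and 5 adjusted over the list alone (adjusted p = 0.581), with Ctss at 2.46 ± 0.21 and Aif1 at −2.34 ± 0.24. Vascular markers had 3 and 4 of 14 by either adjustment (adjusted p = 0.748), with Pdgfrb at 2.04 ± 0.19, Cdh5 at 1.44 ± 0.21 and Rgs5 at −1.84 ± 0.37. Choroid plexus and ependymal markers had 1 and 1 of 10, 0 and 1 adjusted over the list alone (adjusted p = 0.950), with Ccdc153 at −2.04 ± 0.18 and the ciliary regulator Foxj1 at 0.73 ± 0.20. Blood cell markers had 0 and 4 of 10 by either adjustment (adjusted p = 0.220), with S100a8 at −2.26 ± 0.55, S100a9 at −1.40 ± 0.26 and the globin Hbb-b2 at −1.19 ± 0.28. Calls were lost without CPEB3 IgG replicate 1 for Bcl11b (−1.24), Tbr1 (−1.22), Calb2 (−3.74), Dlx2 (1.505), Ermn (−1.77), Cdh5 (1.35), Foxj1 (0.54), S100a9 (−1.62) and Hbb-b2 (−1.42). They were lost without CPEB3 IgG replicate 2 for Calb2 (−2.42), Dlx2 (2.73), Cdh5 (1.52), Foxj1 (0.92), S100a8 (−1.57), S100a9 (−1.19) and Hbb-b2 (−0.96). They were also lost without control IgG replicate 1 for Calb2 (−2.09), Foxj1 (0.81), S100a8 (−1.90) and Hbb-b2 (−0.92), and without control IgG replicate 2 for Dlx2 (1.58) and Foxj1 (0.65). With spike-in scaling the calls of Bcl11b (−0.71), Tbr1 (−0.95), Npy (−1.21), Ermn (−1.305), Cnp (−1.16), Rgs5 (−1.19), Ccdc153 (−1.399), Foxj1 (1.37), S100a9 (−0.76) and Hbb-b2 (−0.54) were lost. Over all settings Foxj1 lost its call in 8, Calb2 in 7 and Dlx2, Hbb-b2 and S100a8 in 6 each. Second probes of Aldh1l1 (0.59) and Ermn (0.19) were not called, and Bcl11b lost its call with the mean of its probes (−0.19). The median and mean differed in sign for the excitatory list (0.08 and −0.09), and both lay below 0 for the oligodendrocyte list (−0.06 and −0.10), whose test pointed upward.

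Probes of the same gene often differed. Of 1758 genes with several probes whose brightest probe was called higher, the second brightest was also called higher in 614, called lower in 174 and not called in 970. Of 1438 genes whose brightest probe was called lower, the second was called lower in 685 and higher in 72. Between the outermost probes of a transcript, the 3′ probe had the more positive difference, by a median of 0.14 log2 units for pairs under 500 nt apart (95% bootstrap interval 0.12 to 0.18, 1277 pairs) and 1.19 for pairs at least 3000 nt apart (1.105 to 1.27, 584 pairs). The pair of Nr3c1 probes had a gap of 1.35 at 2542 nt, which lies at percentile 66.7 of the 2016 pairs at least 1000 nt apart.

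**Figure D3:**
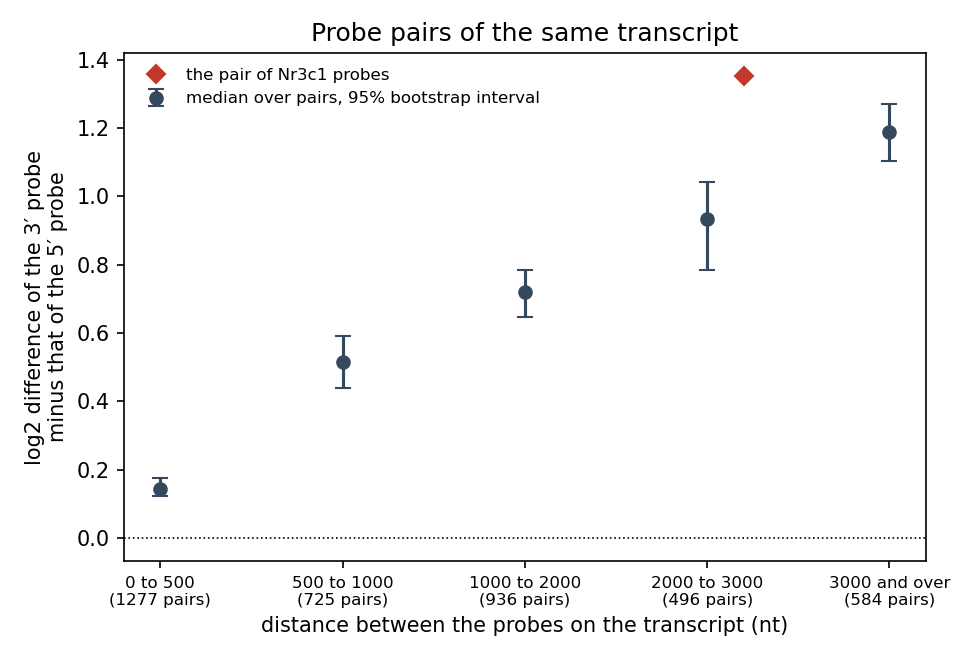
Log2 difference (CPEB3 IgG minus control IgG) of the 3′ probe minus that of the 5′ probe of the same transcript (vertical axis) by the distance between them in nucleotides (horizontal axis), as medians with 95% bootstrap intervals, with the Nr3c1 pair as a diamond. The median rises from 0.14 under 500 nt to 1.19 at 3000 nt and over, and the Nr3c1 gap is 1.35.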

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

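The comparison of control probes outside the main measurement was chosen after the data were seen. Of 127 external control probes on the array, 57 were well above background on any array, and 1 of them, ERCC-00170_100, was higher on both CPEB3 IgG arrays than on both control IgG arrays. Its levels relative to the 75th percentile were −2.48 and −1.99 with CPEB3 IgG and −3.24 and −2.49 with control IgG, a difference of 0.628 on the log2 scale. By chance, 16.7% of probes would order the 4 arrays in this way, so 1 of 57 is no excess, and no biological explanation was tested. Control probes lower on both CPEB3 IgG arrays than on both control IgG arrays were not counted. They include ERCC-00018_67 (−3.936), ERCC-00113_271 (−3.41), ERCC-00014_76 (−1.568), ERCC-00148_99 (−1.244), ERCC-00137_95 (−1.243) and DCP_22_9 (−1.144). For ERCC-00018_67 and ERCC-00113_271 the control IgG replicates lay far apart. Their levels were 0.37 and 2.804 in control IgG replicate 1, and −4.005 and −1.989 in replicate 2. The count therefore does not show that the control probes were level between the groups.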

How the results depend on the processing

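The restriction to RefSeq-matched entries, the other Nr3c1 probe and the test on other splits of the arrays were chosen after the result was seen. The counts of higher and lower entries (5309 and 5599) stayed within 1.5 times under normexp, quantile, cyclic loess, both filters, the mean of probes, the intensity trend and the RefSeq restriction (4734 and 3845). Lower entries numbered 3137 with median scaling and 782 with spike-in scaling, which move the median of all genes by 0.29 and 0.65 on the log2 scale (quantile 0.17, cyclic loess 0.15). Without scaling the counts were 3110 and 3629, at adjusted p 0.01 they were 2643 and 1794, and 3522 lower entries differed at least 2-fold. Leaving out single arrays gave 2492 to 4320 higher and 2019 to 4466 lower entries, where the lone array is assumed to vary like the other group, and 8 to 11 lists. The other settings with the preset correlation passed 8 to 13 lists, and 0 passed with an estimated correlation. Glutamate receptor, RNA-binding, immediate early, ER chaperone, oxidative phosphorylation, proteasome and cytoskeletal lists passed in all 17 settings with the preset correlation, potassium channels in 15, chromatin regulators in 13 and E3 ligases in 10. Of lists that did not pass in the main setting, histones passed downward in 8, GABA genes upward in 3 and calcium, cAMP and MAP kinase genes upward in 1. The Nr3c1 difference was 0.98 to 1.15 with single arrays left out, 1.03 without scaling, 0.386 with the mean of probes and −0.290 at the other probe. Of 1854 comparisons of the other 124 genes taken by the rule or added to it, 1692 kept their side, 145 lost and 5 gained the call and 12 changed sign. These were Dlg4 (−0.073 with quantile, −0.00856 with cyclic loess, −0.066 to 0.234 with single arrays left out, with −0.032 without control IgG replicate 2 and the lowest without CPEB3 IgG replicate 2), Trpv1 (0.069, 0.068 and 0.34 with quantile, cyclic loess and spike-in), Grin2b (0.11, 0.47 and 0.20 with median, spike-in and the mean of probes), Gas5 (−0.047 with the mean of probes) and Xbp1 (0.025 with spike-in). Of these, Gas5 and Xbp1 had passed the test. The cause was not tested. With the replicate number as a replicate block, 5759 entries were higher, 6654 lower, 10 lists passed and Nr3c1 stayed at 1.06. Same-numbered arrays deviated together with a correlation of 0.39, and with 2 arrays per group both pairs give this same value. The 2 pairs are too few to tell whether the shared numbers pair the arrays. The replicate number also matched the second number of the slide position, so a replicate block and that position cannot be told apart. Of the 3 splits of the 4 arrays into 2 and 2, only the real one gave as many calls, 1 of 3, with 10908 against 0 in the highest other, where limma gave 342 and 32 entries an unadjusted p under 0.05, and 3 splits are too few for a share under 0.05. The other splits put a CPEB3 IgG and a control IgG array in each group. The difference between the antibodies then enters the spread, so their low counts were largely fixed in advance and decide nothing. Signal over background limits dim probes, since 15065 probes were filtered out.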

Other observations

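The gene families, the pairs matched in brightness, the split of pairs into equal groups, the position of dim probes, the motif count, the lists over genes with a position alone, the pairs under 500 nt and the form of the A+T test were chosen after results had been seen, and the shifts of the lists and the raw Nr3c1 signals were known when the other tests were set. Families were taken from gene symbols, with at least 15 tested members, and 16 of 104 passed camera with the preset correlation but 0 with an estimated one, where the lowest adjusted p was 0.637. The values that follow are with the preset correlation. Family members were all RefSeq-matched, but the comparison was with all 27687 entries. Of matched entries 25.6% were higher and 19.9% lower, against 6.12% and 16.9% of genomic intervals, which favours upward families. No family test over matched entries alone or with a trend removed is reported here. Solute carriers (Slc genes) were higher for 117 and lower for 25 of 312 (adjusted p = 8.5e-06), with a median log2 difference of 0.40, and Tmem genes for 87 and 21 of 205 (adjusted p = 8.5e-06, median 0.50). Palmitoyltransferases of the Zdhhc family had 11 and 1 of 19 (adjusted p = 0.000488), cadherins 12 and 1 of 20 (adjusted p = 0.00203) and Galnt glycosyltransferases 9 and 1 of 16 (adjusted p = 0.00205). Mitochondrial ribosomal protein genes (Mrpl and Mrps) were lower for 49 and higher for 8 of 75 (adjusted p = 0.000194), with a median of −0.95.

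The log2 differences of the Nr3c1 probes lay 1.35 apart. Over 495 other genes with probes 2 to 3 kb apart, the 3′ probe exceeded the 5′ probe by a median of 0.932 (95% interval 0.778 to 1.047), above the 0.676 set as the limit, so a general loss of signal far from the 3′ end with CPEB3 IgG may account for much of it. Probes at least 4-fold dimmer than the brightest probe of a higher gene read 0.02 of its difference (−0.02 to 0.067), which goes with dimness too. These genes were taken because their brightest probe was called higher, so a smaller value at their other probes is partly built in. The gap was 0.79 in 440 pairs at least 1000 nt apart and within 2-fold in brightness. Without the limit on brightness it was 0.72 for pairs 1000 to 2000 nt apart and 1.19 at 3000 nt and over. Dim probes 3′ of the brightest had a median log2 difference of 0.66 (58 probes), against 1.26 at the brightest. Those 5′ of it had −0.09 (492 probes), against 1.38. Pairs at least 1000 nt apart were also split into 3 equal groups by their mean difference. The gap was 0.80 among the lowest, 0.80 among the middle and 1.08 among the highest. Over the same distances it was 1.52 where the 3′ probe was called higher and 0.024 (−0.159 to 0.182) where it was called lower. That split is on a value that enters the gap itself. RNA cut or lost toward the 5′ end during CPEB3 precipitation, binding of CPEB3 to 3′ fragments and transcripts with other 3′ ends were not tested apart.

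Lists shifted in opposite ways, and the position of the probe on its transcript, a stand-in for transcript length, correlated with the difference at a Spearman rho of 0.36 across 17215 genes, which are not independent replicates. With that trend removed, the oxidative phosphorylation and proteasome lists kept 0.787 of their shift (0.724 to 0.907), above the limit of 0.5. This argues against the trend with probe position as the whole cause. Length itself was not measured, and removing an imprecise stand-in can leave part of a length effect, so length is not excluded. The glutamate receptor and RNA-binding lists kept 0.678 (0.369 to 0.857). That interval spans the limit of 0.5, so for these lists the part of length cannot be told apart. Intervals in this paragraph resample a list's genes as if independent, and leave out the spread between arrays. The median of glutamate receptors, relative to all genes, went from 0.84 to 0.61 (adjusted p 0.00504 before and 0.0717 after), those of potassium channels (0.53 to 0.21), chromatin regulators (0.27 to −0.10) and E3 ligases (0.53 to 0.003) had not passed over these genes even before (0.079, 0.148 and 0.156), while RNA-binding regulators (1.11 to 0.73, 0.00994), immediate early genes (1.06 to 0.998, 0.00686) and ER chaperones (0.88 to 0.89, 0.000894) still passed and the cytosolic ribosomal list newly did (0.01 to 0.45, 0.00994). Removing the trend with GC content left 1.001 (0.913 to 1.214) and 0.745 (0.648 to 0.971) of the shifts, and removing that with signal level left 1.111 (1.053 to 1.198) and 0.80 (0.67 to 0.90), which argues against either as the whole cause. The list tests with a trend removed used the preset correlation only. Before any trend was removed, 0 lists passed with an estimated correlation, which was 0.512 for the cytosolic ribosomal list. Selective binding by CPEB3 stays open as a hypothesis.

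A hypothesis on sequence was tested because CPEB proteins are known to recognise uridine-rich elements. In a linear model over 16444 genes with signal and position held, slopes on the probe's T and A shares were 0.0455 and 0.0195. The T slope exceeded the A slope by 0.026 log2 units per percentage point (0.0237 to 0.0284). Intervals in this paragraph are over genes or probe pairs, which are not independent replicates, and leave out the spread between arrays. The gap as a share of the larger slope was 0.571 (0.519 to 0.624). Both slopes are relative to C, the base left out of the model, so this share depends on that choice. The gap of 0.026 does not, and it argues against A+T content alone, provided that both bases count alike. An effect of hybridisation or amplification that differs between T and A was not tested. The motifs TTTTAT or TTTTAAT stood in 10.7% of the probes of higher genes (464 of 4320), 2.46% of lower (81 of 3296) and 4.81% of those not called (425 of 8828). In the same order, the mean T share of these probes was 33%, 26.4% and 29.7%, and their median position 2902, 1384 and 1896 nt. No count matched on composition or position was made, so these counts cannot separate the motifs from either. Within 1276 pairs of probes under 500 nt apart on the same transcript, the excess of the T over the A slope was 0.0122 (0.00785 to 0.0165). This argues against distance from the 3′ end as the whole cause of the excess. Relative to C, the A slope was −0.00778 ± 0.00319 (SE), and the T slope of 0.0044 ± 0.00308 (SE) was not told from 0. Both slopes would change with another base left out, so the excess cannot be assigned to T or to A. Uridine-rich binding may account for a part of the slope of 0.026 and stays a hypothesis, and the place of probes in 3′ UTRs was not analysed here.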
